A study of Mus musculus with 4 samples.

How the data were processed

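RNA from cultured mouse T cells was hybridised to 4 Affymetrix expression arrays, 2 from cells named Tc1 and 2 from cells named Tc9. Per the labels' protocols, the cells were grown under a Tc1 or a Tc9 cytokine condition, total RNA was taken with Trizol, and a biotin label was added by the Affymetrix protocol. Cytokines, culture times and the source of the cells are not given in the sources used here. Groups and replicate numbers came from the sample titles, which give each group the numbers 1 and 2. Nothing in the labels says that the replicates came from separate cultures or animals, so the spread between these samples may be technical. The p-values of the gene tests rest on that spread and on spread borrowed from other genes. They are not shown to hold for other cultures or animals.

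The authors deposited 1 intensity for each of 28846 probe sets on each array. The background correction, summarization and software that gave the deposited intensity values are not given in the sources used here, and the linear scale was read from the values, all of them positive and up to 13711. The median deposited intensity was 37.1 and 37.9 on the Tc1 and Tc9 arrays numbered 1, and 57.3 and 57.1 on those numbered 2. The written values held a median of 10 digits on the arrays numbered 1 and 7 on the others. The 4 arrays were therefore read as 2 pairs processed apart, each holding 1 Tc1 and 1 Tc9 array. The main test did not use the pairs, so a difference between them counts as spread within the groups. Differences are also given with the replicate number as a block, as an alternative, and within each pair. The pair and the replicate number coincide, so a difference between cultures and a difference in processing cannot be told apart.

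Of the probe sets, 6640 were controls and were left out of normalization and tests. Among the other 22206, the platform annotation gave 19572 a single gene symbol and 0 several, and 2634 were unnamed here. All 19572 Entrez identifiers matched the RefSeq gene table used, and 0 symbols changed. No genome build is given for the array, so no coordinates are printed. A gene with several probe sets (55 genes) was represented by the probe set with the highest mean, which left 19505 genes.

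A rule set before the data were examined called for quantile normalization where array medians differed by over 0.5 on the log2 scale. The gap was 0.543 over named probe sets and 0.464 over all probe sets, both after adding 16, so the rule was met only for the first, which are the probe sets tested. Intensities were quantile normalized over the 4 arrays, 16 was added and log2 was taken. Fold changes are on this log2(value + 16) scale, which understates the change of dim genes. They were tested in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with an intensity trend) as Tc9 minus Tc1, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The fit had 2 residual degrees of freedom, to which eBayes added 5.08 prior degrees of freedom. With the block, 1 was left and the prior was infinite, so that every gene of like intensity was given the same spread. Means in the text are of quantile normalized intensities, with SD over n = 2 arrays, and the error of a log2 change is the SE of the fit.

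The 27 gene lists held 494 distinct genes, of which 435 were measured and 59 are not analysed here. The 26 lists with at least 5 measured members were tested against all other genes with limma's camera, 2-sided, at a preset correlation between members of 0.01. Its p-values rest on the spread of the gene statistics over genes, with members taken as nearly independent. They do not measure the spread between arrays. The same test with an estimated correlation, and fry, which tests whether a list's genes move on balance in one direction, were alternatives. The correlation was estimated from the fit without the block, with 2 residual degrees of freedom, so any difference between the pairs enters it. A call lost with it does not show that a list is unshifted. Members past the gene test were counted with adjustment over all genes and adjusted over the list alone. The lists were the type 1 effector program, cytotoxic granules and death ligands, the IL-9 program, the type 2 program, TGF-beta responsive genes, tissue residence, naive and memory T cells, inhibitory receptors, the interferon response, cholesterol synthesis, cholesterol efflux with LXR targets, fatty acid synthesis, fatty acid oxidation, glycolysis, cell cycle, NF-kappaB targets, IL-2 and STAT5 targets, immediate early genes, chemokine receptors, CD8 T cell identity, and markers of B cells, myeloid cells, CD4 T cells, NK cells, gamma-delta T cells, mast cells and basophils, and erythroid cells and platelets.

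The genes named are 11 chosen by function (Il9, Ifng, Tbx21, Eomes, Gzmb, Prf1, Il10, Cd8a, Cd8b1, Cd4 and Cd3e), the 10 largest rises and 10 largest falls among genes past the threshold in which both Tc9 arrays lay on the same side of both Tc1 arrays, and up to 4 past the threshold with the largest change from each list, or the member with the smallest p where none passed. Gene models without a proper name and antigen receptor segments were passed over. Genes named outside this rule are said to be so where they appear.

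The 4 arrays limit the precision. Per array, between 34.8% and 37.7% of named probe sets lay above the 95th percentile of 5222 negative control probe sets. A signal below that percentile is dim, but a difference can still be called there. Fgf2, named outside the rule, lay below it on all 4 arrays and still passed (17.2 against 132, limma adjusted p = 0.0123). The fit was tested on simulated values for the 19505 genes of this comparison. Without the block it recovered 16%, 82%, 98% and 100% of genes changed by 1, 2, 3 and 4 on the log2 scale, with 0 false calls, and with the block 100% of each with 10 false calls. Simulated noise was independent between genes, with an SD set by intensity alone and taken from the residuals of the fit with the block. The fit with the block assumes such an SD, so its 100% was favoured by the simulation. It does not show how accurate the calls with the block are in these data. Of 5 simulated lists of 20 genes shifted by 0.5, camera found 5 with the preset correlation and 4 with the estimated one, with 0 false calls among 20 unshifted lists in both. These lists were random genes with independent noise. They cannot show how often lists whose members vary together are called falsely. The alternatives were the values as deposited, median centring, filters at the 25th and 50th percentile of intensity, the mean of a gene's probe sets, eBayes without the trend or with robust settings, a minimum fold change of 2 (a log2 change of 1), pseudocounts of 1 and 32, the replicate block, and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.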

Results

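Gene expression was compared between mouse T cells cultured under a Tc1 and under a Tc9 cytokine condition, with 2 arrays per group. In the field, Tc1 names CD8 T cells that make interferon gamma and kill target cells, and Tc9 names CD8 T cells that make interleukin 9. The stated question was how their gene expression differs. After quantile normalization, log2 values correlated across genes with r = 0.988 between the Tc1 replicates, 0.985 between the Tc9 replicates, 0.987 between the Tc1 and Tc9 arrays numbered 1, and 0.990 between those numbered 2. Genes are not independent replicates, and arrays sharing a number were about as alike as arrays sharing a cell type.

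Tc9 cells held less transcript of the effector genes Gzmb, Prf1 and Ifng than Tc1 cells and more of Ccr8, Nt5e and Itgae. Gzmb, which encodes the granule protease granzyme B, fell from 6872 ± 119 (SD, n = 2) in Tc1 to 469 ± 3.71 in Tc9, or 14.2-fold on the log2(value + 16) scale used for all folds, which understates those of dim genes. Il12rb2, a subunit of the interleukin 12 receptor, went from 1170 ± 488 to 110 ± 45.4, or 9.35-fold lower. Both of its Tc9 signals lay below the 95th percentile of the negative controls, so the size of that fold is uncertain. Ccr8, a chemokine receptor, rose from 18.6 ± 4.79 to 1377 ± 284, or 40.0-fold, and Itgae, the CD103 integrin chain that binds E-cadherin, rose 11.6-fold from 141 ± 12.3 to 1814 ± 94.8. Ccr8 and Itgae lay below the 95th percentile of the negative controls on both Tc1 arrays, so the size of their folds is uncertain. By limma, 110 of 19505 genes passed the adjusted threshold, 75 higher and 35 lower in Tc9, with a median absolute log2 change of 1.72 (range 0.88 to 5.32). At an unadjusted p under 0.05 there were 1030 genes.

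**Figure D1:**
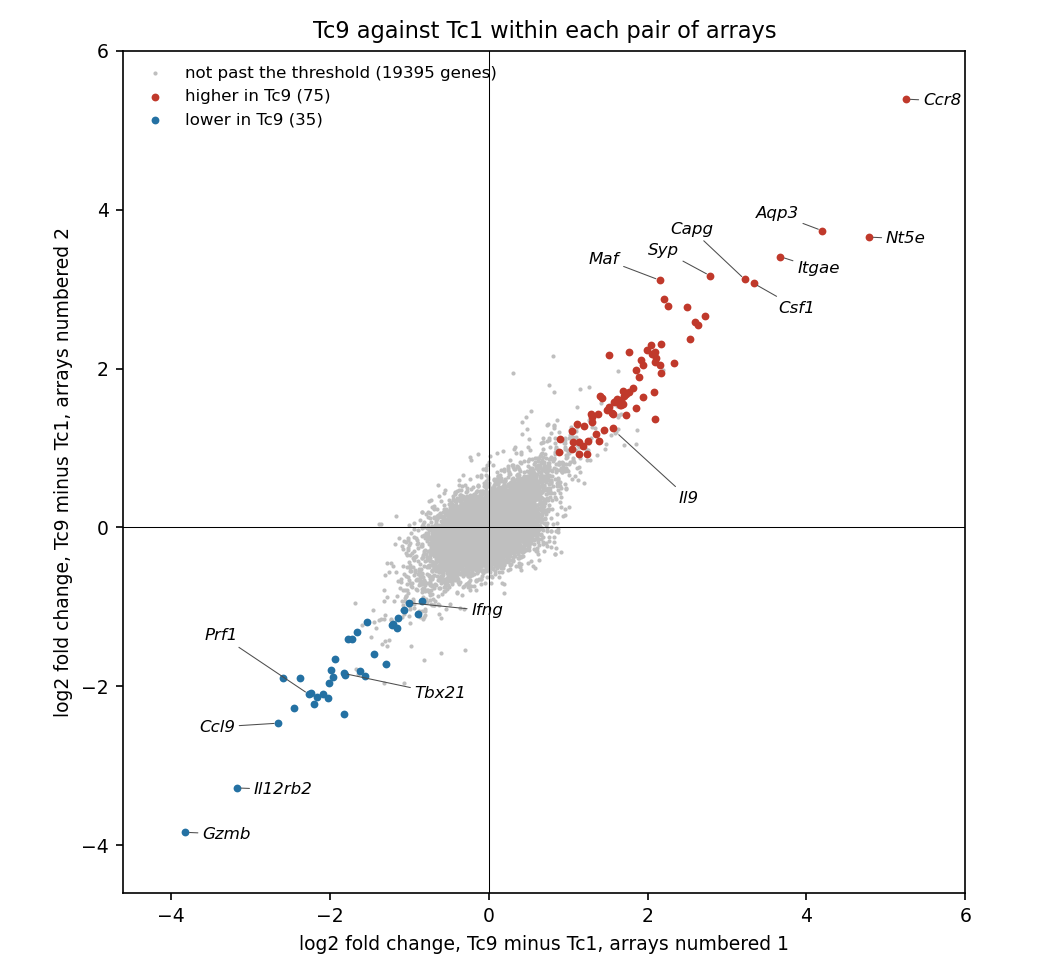
Log2 fold change of each gene, Tc9 minus Tc1, in the arrays numbered 1 (horizontal axis) and those numbered 2 (vertical axis). Each point is 1 of 19505 genes, in red for the 75 past the threshold and higher in Tc9, in blue for the 35 lower, and in grey for the others. All 110 coloured genes lie on the same side of 0 in both pairs, with Ccr8 highest and Gzmb lowest. They were called on these same arrays, which favours such agreement.

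Among the 10 largest rises, Nt5e, the surface enzyme CD73 that makes adenosine from AMP, rose by 4.22 ± 0.27 on the log2 scale (SE, limma adjusted p = 0.00188; 4.79 and 3.65 in the pairs numbered 1 and 2). Aqp3, a water and glycerol channel, rose by 3.97 ± 0.24 (adjusted p = 0.00181; 4.20 and 3.73 in the pairs). Csf1, the macrophage growth factor, rose by 3.20, and Capg, an actin capping protein, by 3.17. Syp, a synaptic vesicle protein, rose by 2.98, Tgfbr1, a TGF-beta receptor chain, by 2.69, Cd72, a receptor best known from B cells, by 2.63, and Maf, a transcription factor of interleukin 4 and interleukin 10 expression, also by 2.63. For Ccr8 the rise was 5.32 ± 0.23 (adjusted p = 0.000371; 5.25 and 5.39 in the pairs). In both Tc1 arrays the signals of Ccr8, Nt5e, Aqp3, Itgae, Csf1, Tgfbr1 and Maf lay below the 95th percentile of the negative controls, so these folds start from a level near background.

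The falls were led by Gzmb, at -3.83 ± 0.12 (limma adjusted p = 0.000109; -3.82 and -3.84 in the pairs), and Il12rb2, at -3.22 ± 0.35 (adjusted p = 0.0121). Ccl9, a chemokine, fell from 1372 ± 33.1 to 221 ± 27.1 (log2 change -2.56), and Lif, a cytokine of the interleukin 6 family, from 1206 ± 174 to 248 ± 33.3 (-2.21). Prf1, the pore-forming protein of cytotoxic granules, fell by 2.18. Ly6c2, a surface protein of effector and memory T cells, fell by 2.36, Calhm6 by 2.24, Iigp1, an interferon-inducible GTPase, by 2.16, Galnt3, which starts O-glycosylation, by 2.15, and Ms4a4c by 2.13. In both Tc9 arrays Il12rb2, Ly6c2, Calhm6, Prf1, Galnt3 and Ms4a4c lay below the 95th percentile of the negative controls.

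With the replicate number as a block, 2674 genes passed (1236 higher, 1438 lower), among them all 110, and 1426 without the intensity trend as well. The block leaves each log2 change as it was, so the direction of the 110 could not differ. At least 2-fold differences in both pairs were found for 112 genes higher and 58 lower in Tc9, and for 0 genes in opposite directions, a count without a test. Fold changes in the pairs correlated across all genes with r = 0.668 (Spearman's rho 0.412) and across the 110 genes with r = 0.989. The 110 were called on these same arrays for differences that are large beside the spread within groups. Their likeness between the pairs therefore follows in part from that choice. The split of 75 higher and 35 lower became 13 and 3 with the values as deposited and 30 and 22 with median centring. Of the 37 named genes past the threshold, 26 lost their call with the values as deposited; Aqp3, Capg, Ccr8, Csf1, Gzmb, Il12rb2, Itgae, Ldlrad4, Maf, Nt5e and Syp kept it. Without the intensity trend 10 lost it (Ifng, Il12rb1, Il12rb2, Il6ra, Maf, Prf1, S1pr1, Scd1, Socs2 and Tbx21), and with median centring 7 (Ccr9, Gbp7, Il12rb1, Il6ra, S1pr1, Scd1 and Serpinb9), each in its direction as before. Without the Tc1 array numbered 1 or 2, 186 and 191 genes passed, and without the Tc9 array numbered 1 or 2, 247 and 274, each including all 110.

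The transcription factors and cytokine that define type 1 cells were lower in Tc9. Tbx21, encoding T-bet, fell from 609 ± 106 to 160 ± 31.0 (log2 change -1.83 ± 0.22, limma adjusted p = 0.0168; -1.83 and -1.84 in the pairs). Eomes, its relative in memory and effector CD8 cells, fell from 1050 ± 1.18 to 254 ± 6.22 (-1.98 ± 0.15, adjusted p = 0.00383; -2.01 and -1.96 in the pairs). Ifng, encoding interferon gamma, fell from 4388 ± 439 to 2217 ± 160, a log2 change of -0.98 ± 0.13 (adjusted p = 0.0252; -1.01 and -0.95 in the pairs) that left it at a high signal in both groups. The calls of Tbx21, Eomes, Ifng and Il12rb1 were lost with the values as deposited (limma adjusted p = 1 for each). Those of Tbx21 (adjusted p = 0.0603), Ifng (0.134) and Il12rb1 (0.0970) were lost without the intensity trend, and that of Il12rb1 also with median centring (0.363) and the robust variance model (0.0505). Ifng, at less than a 2-fold change, also missed the alternative that asks for an absolute log2 change of at least 1. Of the 20 measured genes of the type 1 effector program, 7 fell and 1 rose (adjusted over the list alone, 9 and 2). On all 4 arrays 7 of the 20 lay below the 95th percentile of the negative controls. Il12rb1, the partner chain of Il12rb2, fell by 1.23. The riser, named outside the rule, was Id2, an inhibitor of E proteins in effector cells, at 1.11. The mean log2 change of the list was -0.59 (-0.57 and -0.60 in the pairs; camera adjusted p = 2.03e-08, with the block 9.75e-27), with adjusted p = 0.157 with an estimated correlation, and -0.91 over members of a single list.

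Among 22 genes of cytotoxic granules and death ligands, 3 fell (Gzmb, Prf1 and Serpinb9) and 1 rose (adjusted over the list alone, 6 and 3). On all 4 arrays 12 of the 22 lay below the 95th percentile of the negative controls, where a change could not be measured reliably. Serpinb9, an inhibitor of granzyme B, fell from 1256 ± 111 to 372 ± 1.53 (log2 change -1.71). Ctsw, the lysosomal protease cathepsin W of cytotoxic lymphocytes, rose from 447 ± 36.8 to 1980 ± 78.7 (2.11). The list mean was -0.36 (-0.39 and -0.33 in the pairs; camera adjusted p = 0.00374, with the block 1.31e-09). It had adjusted p = 0.202 with an estimated correlation, and adjusted p = 0.103 over the brighter 50% of genes.

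Interferon-inducible genes were lower in Tc9. Of 31 measured genes of the interferon response list, 6 fell (adjusted over the list alone, 14), and 30 had a negative log2 change. Gbp2, a guanylate-binding protein that acts against intracellular microbes, fell from 3338 ± 105 to 771 ± 24.2 (log2 change -2.09), Gbp3 by 1.93 and Gbp7 by 1.89, beside the related GTPase Iigp1. The list mean was -0.67 (-0.65 and -0.70 in the pairs; camera adjusted p = 2.14e-24, with the block 5.35e-43), with adjusted p = 0.157 with an estimated correlation. Gbp2, Gbp3 and Gbp7 are close relatives, and sharing of signal between their probe sets was not examined.

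The TGF-beta responsive genes were higher in Tc9, with a mean log2 change of 1.26 (1.34 and 1.19 in the pairs; camera adjusted p = 8.45e-28, with the block 3.83e-72), with adjusted p = 0.157 with an estimated correlation. Of 20 measured members 7 rose (adjusted over the list alone, 13), and 18 had a positive log2 change. They included Nt5e, Itgae and Tgfbr1, and Ldlrad4, an inhibitor of TGF-beta signalling, which rose from 29.2 ± 4.70 to 257 ± 30.6 (2.59), below the 95th percentile of the negative controls on both Tc1 arrays. In the tissue residence list, Itgae alone of 13 genes rose (adjusted over the list alone, 4 rose and 2 fell), and the mean was 0.49 (0.44 and 0.54 in the pairs; camera adjusted p = 0.00374, with the block 1.30e-06), with adjusted p = 0.392 with an estimated correlation. The median of the 13 was 0.14, and 4 of them lay below the 95th percentile of the negative controls on all 4 arrays. Of 16 naive and memory T cell genes, 2 rose (adjusted over the list alone, 7): S1pr1, the receptor for lymph node exit, by 1.79 and Il6ra, the interleukin 6 receptor, by 1.68. Both lay below the 95th percentile of the negative controls on the Tc1 arrays and lost their calls as deposited (limma adjusted p = 1 for both), with median centring (0.0994 and 0.122) and without the intensity trend (0.0727 and 0.0559). That list's mean was 0.47 (0.47 and 0.47 in the pairs; camera adjusted p = 8.23e-07, with the block 4.76e-10), with adjusted p = 0.186 with an estimated correlation.

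The chemokine receptor and type 2 lists, which share Ccr8 and Ccr4, were both higher in Tc9. Of 23 chemokine receptor and homing genes, 4 rose (adjusted over the list alone, 7), among them Ccr4, a receptor of skin-homing and type 2 cells, from 235 ± 68.8 to 1421 ± 72.1 (log2 change 2.54), and Ccr9, the gut-homing receptor, from 236 ± 24.1 to 711 ± 19.4 (1.53). The mean was 0.66 (0.65 and 0.68 in the pairs; camera adjusted p = 1.15e-07, with the block 8.73e-19), with adjusted p = 0.157 with an estimated correlation. The median was 0.12, and 10 of the 23 lay below the 95th percentile of the negative controls on all 4 arrays. Of 17 type 2 genes, 5 rose (adjusted over the list alone, 6 rose and 1 fell), including Ccr8, Maf, Ccr4 and the Ccr8 ligand gene Ccl1, from 549 ± 30.2 to 2390 ± 126. The type 2 cytokine genes, named outside the rule, had log2 changes of -0.20 for Il4, -0.04 for Il5 and 0.02 for Il13. All 3 lay below the 95th percentile of the negative controls on all 4 arrays, so that a change could not be measured reliably. The type 2 mean was 0.80 (0.73 and 0.87 in the pairs; camera adjusted p = 6.83e-07, with the block 9.77e-32), with adjusted p = 0.169 with an estimated correlation. The type 2 median was 0.21, and 9 of the 17 lay below that percentile on all 4 arrays. Of 19 IL-2 and STAT5 targets, Ccr8 and Socs2, a cytokine signalling inhibitor, rose (adjusted over the list alone, 3 rose and 3 fell). The mean was 0.46 (0.48 and 0.44 in the pairs; camera adjusted p = 0.00445, with the block 9.52e-08), with adjusted p = 0.202 with an estimated correlation. The median of these targets was 0.23. Counting only members of a single list, a setting added after the values were seen, ended the calls of the chemokine receptors (mean 0.20, adjusted p = 0.0983), type 2 genes (0.26, 0.129) and tissue residence (0.036, 0.720) and turned the mean of the IL-2 and STAT5 targets to -0.015 (0.402). Over the brighter 50% of genes the means were 1.74 for the type 2 and 1.15 for the chemokine receptor list, against 1.33 for the TGF-beta responsive genes. That filter goes by the mean over all 4 arrays. Ccr8 and Maf, near background in Tc1, stay through their Tc9 signal, while members dim in both groups drop out. The larger means can follow from that selection alone.

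Il9, the cytokine gene that gives Tc9 cells their name, measured 23.4 and 26.5 on the Tc1 arrays and 103 and 81.9 on the Tc9 arrays, a log2 change of 1.40 ± 0.24 (1.60 and 1.20 in the pairs) that missed the threshold (limma adjusted p = 0.0682). It lay below the 95th percentile of the negative controls on all 4 arrays, so that the size of its change could not be measured reliably. It passed with the block (5.01e-15), with a filter at the 25th percentile (0.0454), and without the Tc9 array numbered 1 (0.0217) or 2 (0.00185). Of the 22 genes of the IL-9 program, 0 passed limma over all genes, 4 rose and 1 fell adjusted over the list alone and at an unadjusted p under 0.05, and 6 rose and 2 fell with the block. The smallest p in that list was that of Foxo1, a transcription factor of quiescent and memory T cells, at 456 ± 66.7 and 1012 ± 127 (adjusted p = 0.0527, with the block 9.36e-38; 0.0489 with a pseudocount of 1; between 0.0277 and 6.95e-05 without any 1 of the arrays). On all 4 arrays 12 of the 22 program genes lay below the 95th percentile of the negative controls. The list mean was 0.18 (0.19 and 0.17 in the pairs; camera adjusted p = 0.0220, with the block 0.000621), with adjusted p = 0.250 with an estimated correlation. The call was lost without the Tc1 array numbered 1 (adjusted p = 0.138) and without the Tc9 array numbered 2 (0.153), and with members of a single list (0.171). Il10, which encodes an anti-inflammatory cytokine, measured 23.7 ± 8.15 and 22.3 ± 10.5. It lay below the 95th percentile of the negative controls on all 4 arrays, so that a change in it could not be measured reliably.

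**Figure D2:**
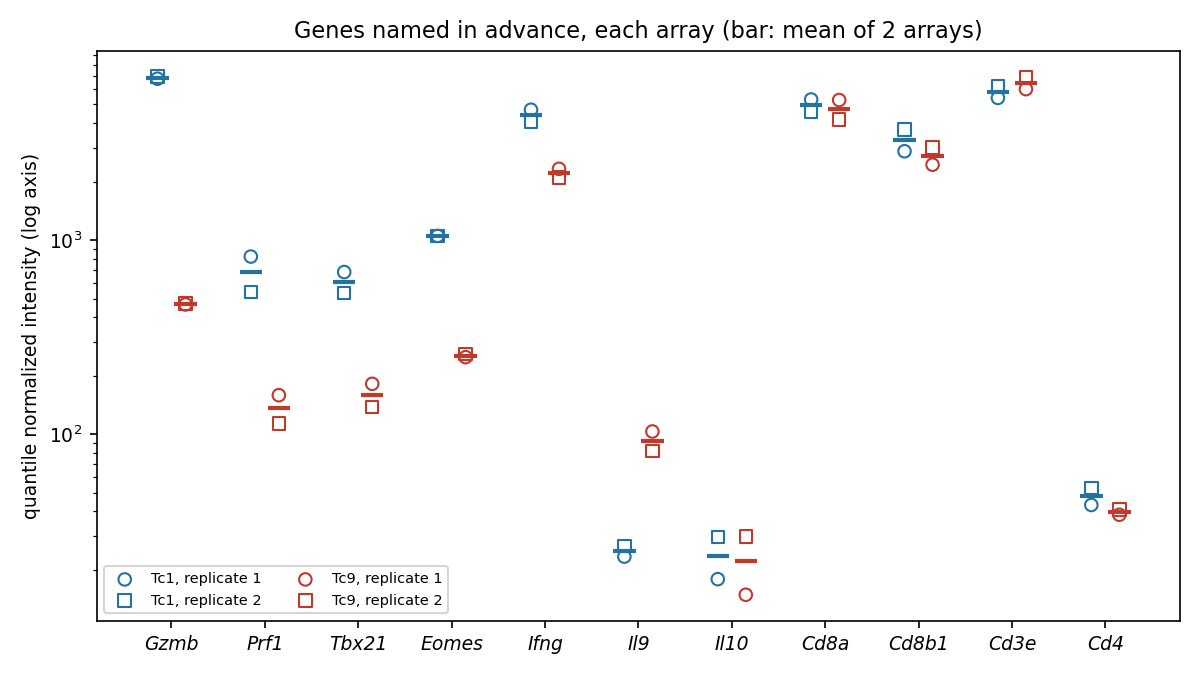
Quantile normalized intensity (log axis) of the 11 genes chosen by function on each array, blue for Tc1 and red for Tc9, circles for replicate 1 and squares for replicate 2, with bars at the means of 2 arrays. Gzmb, Prf1, Tbx21, Eomes and Ifng lie lower on both Tc9 arrays and Il9 higher, at 103 and 81.9 against 23.4 and 26.5, while Cd8a, Cd8b1 and Cd3e lie above 2000 on every array.

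Genes of glucose breakdown and of division were slightly lower in Tc9 as groups, without a member past the gene test. For glycolysis, 20 of 20 genes had a negative log2 change, with a mean of -0.24 (-0.25 and -0.22 in the pairs; camera adjusted p = 8.23e-07, with the block 9.55e-07), with adjusted p = 0.157 with an estimated correlation. By limma 0 of them passed, 3 were lower at an unadjusted p under 0.05 and 12 fell with the block. Hk2, the hexokinase of activated T cells, measured 603 ± 11.6 and 374 ± 54.9 (limma adjusted p = 0.292, with the block 1.18e-10). Of 30 cell cycle genes, 0 passed limma, 8 were lower at an unadjusted p under 0.05, 3 fell adjusted over the list alone, and 16 fell and 1 rose with the block. Aurkb, a mitotic kinase, measured 933 ± 11.6 and 604 ± 15.7 (limma adjusted p = 0.208, with the block 2.87e-12). The cell cycle mean was -0.28 (-0.28 and -0.27 in the pairs; camera adjusted p = 6.09e-08, with the block 1.17e-06), with adjusted p = 0.186 with an estimated correlation. Among 21 NF-kappaB genes 0 passed limma, 2 were higher and 3 lower at an unadjusted p under 0.05, 1 rose and 2 fell adjusted over the list alone, and 3 rose and 7 fell with the block. The riser Map3k14, the kinase of the alternative pathway, measured 565 ± 9.86 and 1015 ± 67.1 (limma adjusted p = 0.0761, with the block 4.23e-22). That mean was -0.11 (-0.090 and -0.13 in the pairs; camera adjusted p = 0.0381, with the block 0.0265), with adjusted p = 0.470 with an estimated correlation, and the call was lost without the Tc1 array numbered 1 (0.304) or 2 (0.0753) or the Tc9 array numbered 2 (0.572).

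In the list of cholesterol efflux and LXR targets, 1 of 13 genes rose (adjusted over the list alone, also 1), namely Scd1, which makes monounsaturated fatty acids, from 89.5 ± 9.97 to 366 ± 86.3 (log2 change 1.84, adjusted p = 0.0252; 1.51 and 2.17 in the pairs). Scd1 lay below the 95th percentile of the negative controls on both Tc1 arrays and lost its call as deposited (limma adjusted p = 1), with median centring (0.0890) and without the intensity trend (0.0600). The 13 genes had a median log2 change of 0.077, against 1.84 for Scd1, and the list without Scd1 was not tested. On all 4 arrays 7 of the 13 lay below the 95th percentile of the negative controls. The list had a mean of 0.23 (0.19 and 0.27 in the pairs), a camera adjusted p of 0.0556, just over the threshold, and 0.314 with an estimated correlation. It passed with the block (adjusted p = 0.0265), the values as deposited (0.0445), median centring (0.0201), a filter at the 50th percentile (0.0243, mean 0.41) and a pseudocount of 1 (0.0489), and without the Tc1 array numbered 1 (0.00959). Cholesterol synthesis (20 genes, mean -0.07, camera adjusted p = 0.401), fatty acid synthesis (15 genes, -0.07, 0.401) and fatty acid oxidation (19 genes, 0.07, 0.233) were not called. Limma passed 0 members of each, against 1, 2 and 2 genes at an unadjusted p under 0.05 and 7, 4 and 5 with the block, and 0 adjusted over the list alone. Over all 19505 genes, 1030 had an unadjusted p under 0.05 and 2674 passed with the block. Whether the counts in these lists exceed those shares was not tested. Their members with the smallest p were Lss, an enzyme of sterol ring closure, the desaturase Fads2, and Cpt1a, the mitochondrial importer of fatty acids. Their log2 changes were -0.42, -0.62 and 0.57, with limma adjusted p = 0.864, 0.602 and 0.450. With the block the adjusted p were 7.49e-09, 4.00e-05 and 6.85e-08. With an array left out the means of the 3 lists ran from -0.10 to -0.047, -0.10 to -0.033 and 0.019 to 0.12, none past the threshold. With median centring cholesterol synthesis had -0.12 and fatty acid oxidation 0.044.

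**Figure D3:**
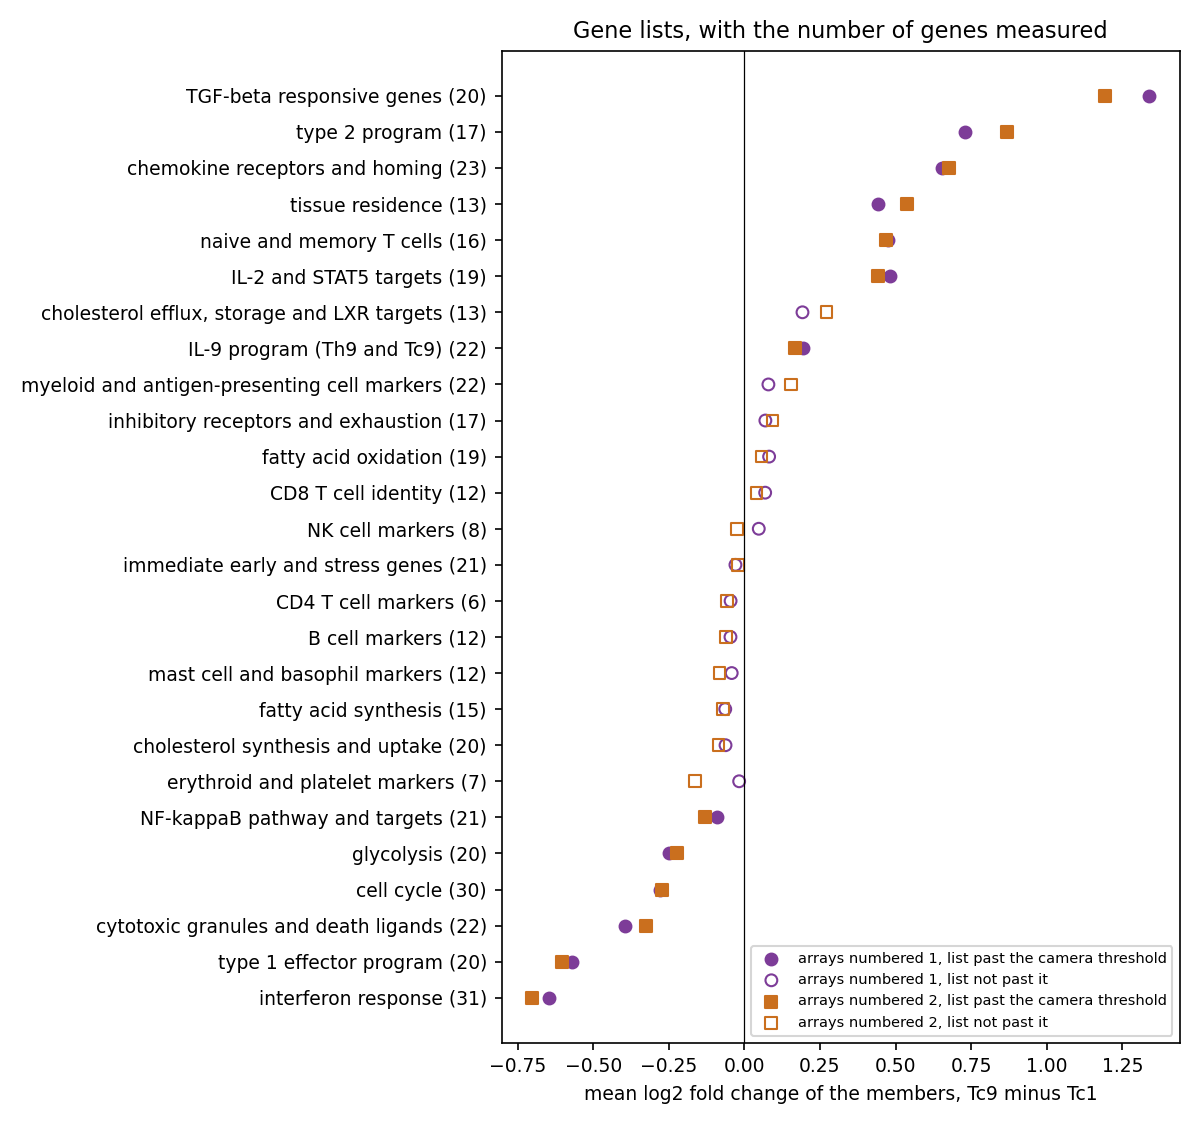
Mean log2 fold change of each of the 26 tested lists, Tc9 minus Tc1, in the arrays numbered 1 (circles) and 2 (squares), with the number of measured genes in brackets and filled symbols for lists past the camera threshold with the preset correlation. TGF-beta responsive genes lie highest, at 1.34 and 1.19, and the interferon response lowest, at -0.65 and -0.70.

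The CD8 T cell genes were bright on all 4 arrays, while markers of other cell types lay mostly near background. A change in such dim markers could not be measured reliably. Cd8a measured 4954 ± 497 in Tc1 and 4725 ± 773 in Tc9, Cd8b1 3297 ± 604 and 2727 ± 395, and the T cell receptor component Cd3e 5792 ± 547 and 6456 ± 648, none past the limma threshold. Cd8b1 and Cd3e passed with the block (adjusted p = 4.70e-06 and 0.00176), but not with the block and no intensity trend (0.162 and 0.455). Cd4, at 48.0 ± 6.90 and 39.7 ± 1.81, lay below the 95th percentile of the negative controls on all 4 arrays. The CD8 identity list (12 genes, mean 0.05, camera adjusted p = 0.390) held 0 genes past limma over all genes. It held 3 genes at an unadjusted p under 0.05 and 9 with the block. Adjusted over the list alone there was 1 riser, Cd3d (0.54, limma adjusted p over all genes = 0.229, with the block 1.11e-13). Mean changes were -0.05 for B cell markers (12 genes, camera adjusted p = 0.551), 0.12 for myeloid and antigen-presenting cell markers (22 genes, 0.0761), -0.05 for CD4 T cell markers (6 genes, 0.725), 0.01 for NK cell markers (8 genes, 0.912, camera direction down), -0.06 for mast cell and basophil markers (12 genes, 0.551, median 0.04), -0.09 for erythroid and platelet markers (7 genes, 0.341) and -0.10 for gamma-delta T cell markers (3 genes, not tested). On all 4 arrays, 11 of the B cell, 20 of the myeloid, 4 of the CD4, 5 of the erythroid and platelet and all of the NK, mast cell and gamma-delta markers lay below the 95th percentile of the negative controls, against 0 of the CD8 identity genes. For these 7 lists the means therefore mostly compare signals near background. Limma passed 0 of their genes over all genes. At an unadjusted p under 0.05 there were 2 CD4 markers and 1 mast cell marker and 0 in the rest, and with the block 1 B cell, 2 myeloid, 2 CD4 and 1 mast cell marker. Adjusted over the list alone 1 CD4 marker, Tnfsf8 (-0.69, limma adjusted p over all genes = 0.295, with the block 1.22e-09), passed. The member with the smallest p in the myeloid list was Cst3 (0.35, limma adjusted p = 0.9999). With the block it had 0.00113, and 0.0761 without the intensity trend as well. In the other lists that member was Fcrla (-0.23), Klre1 (-0.19), Gata2 (-0.66, limma adjusted p = 0.741, with the block 0.00145), Pf4 (-0.35) and Sox13 (-0.19). These 5 genes lay below the 95th percentile of the negative controls on all 4 arrays. The myeloid list passed with the values as deposited (adjusted p = 0.0445), median centring (0.0234) and a filter at the 50th percentile (0.0408).

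Inhibitory receptors (17 genes, mean 0.08, camera adjusted p = 0.192) and immediate early genes (21 genes, mean -0.03, median 0.03, 0.551) were not called either. Pdcd1, encoding the inhibitory receptor PD-1, measured 1188 ± 59.1 in Tc1 and 1756 ± 142 in Tc9 (log2 change 0.56, limma adjusted p = 0.236, with the block 1.25e-15), and Gadd45b, a stress-response gene, 718 ± 2.29 and 451 ± 45.6 (-0.66, 0.236, with the block 1.66e-11). Limma passed 0 genes of both lists, also adjusted over the list alone, against 5 and 2 genes at an unadjusted p under 0.05 and 8 and 7 with the block. Without the Tc9 array numbered 1 the inhibitory receptors passed (0.0463), and without the Tc1 array numbered 1 or the Tc9 array numbered 2 their mean was -0.00385 and -0.016. Across the 26 lists, 13 passed camera with the preset correlation, 14 with the block, 8 with fry, and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05.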

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

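The test of overall scale between the pairs of arrays and both tests of the interferon genes were chosen after their results were seen. The other tests of the 3 patterns weighed here and in the other observations were written down first. A comparison of the residual SD of Il9 and a margin around the threshold for its adjusted p were not part of them.

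Among the 2634 transcript clusters without a gene name here, which entered no comparison, 5 passed the threshold in a limma fit of their own (73 at an unadjusted p under 0.05), 2 higher and 3 lower in Tc9. They are of interest as signal outside the named genes, though whether they are separate from those genes was not examined. TC0300000864.mm.2 was higher by 3.49 on the log2 scale, with intensities of 19.2 and 26.1 in Tc1 and 370 and 466 in Tc9. TC0X00000058.mm.2 was higher by 1.94. Both lay below the 95th percentile of the negative controls on both Tc1 arrays, so these differences start from a level near background. TC0300001444.mm.2, at -2.06, TC1500001728.mm.2, at -1.88, and TC0500002895.mm.2, at -1.81, were lower on both Tc9 arrays. The ID TC0300001444.mm.2 comes directly before that of Gbp7 (TC0300001445.mm.2), which was also lower. Likewise TC1500001728.mm.2 comes directly before that of Ly6c1 (TC1500001729.mm.2), also lower. No explanation was tested for the 5 clusters.

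Arrays sharing a replicate number deviated from their group means together, with a correlation across genes of 0.729 after quantile normalization. A difference of overall scale is argued against by that value, since equal distributions remove such a difference. Negative control probes, which serve to measure background, showed the same pattern with a correlation of 0.466, so a difference in hybridization or background between the pairs of arrays remains a candidate explanation. Different cultures behind the numbers stay open: the log2 difference between the numbers had an SD of 0.311 over genes and 0.343 over negative controls, but number and processing coincide, so they cannot be told apart.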

How the results depend on the processing

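The replicate block without the intensity trend, the block on values as deposited, and the lists reduced to members of a single list were added after the values were seen, and the other settings were planned. All 110 genes kept their direction in every setting, except 1 that the filter at the 50th percentile left untested. The cause was not tested except where a setting's construction gives it. The count of 110 (75 higher, 35 lower) became 16 (13 and 3) with the values as deposited, where the scale gap between the pairs enters the spread, 52 (30 and 22) with median centring and 56 (37 and 19) without the intensity trend, of which 15, 52 and 56 were among the 110. In the other planned fits on 4 arrays without a block it lay between 105 and 131. Taking the numbers as pairs, the replicate block gave 2674 (1236 and 1438), 1426 without the trend (760 and 666) and 2813 on values as deposited (1271 and 1542). Same-numbered arrays deviated together with a correlation of 0.729 across genes (0.840 as deposited), but 2 pairs are too few to settle a pairing. Leaving out an array gave 186 to 274 genes (120 to 167 higher, 55 to 124 lower); those fits have an infinite prior and assume that the lone array varies like the other group.

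All 13 list calls were lost with the estimated correlation. That estimate rests on 2 residual degrees of freedom and holds any difference between the pairs, so the loss does not show that the lists are unshifted. The means were 1.26 for TGF-beta responsive genes, 0.80 for type 2, 0.66 for chemokine receptors, 0.49 for tissue residence, 0.47 for naive and memory T cells, 0.46 for IL-2 and STAT5 targets, 0.18 for the IL-9 program, -0.11 for NF-kappaB, -0.24 for glycolysis, -0.28 for cell cycle, -0.36 for cytotoxic granules, -0.59 for type 1 and -0.67 for the interferon response. With fry, at the same means, the calls of the IL-9 program (0.18, adjusted p = 0.207), NF-kappaB (-0.11, 0.343), cell cycle (-0.28, 0.0546), naive and memory (0.47, 0.0568) and tissue residence (0.49, 0.0793) were lost. With members of a single list, type 2 (0.26), chemokine receptors (0.20), tissue residence (0.036) and the IL-9 program (0.14) lost their calls, and IL-2 and STAT5 targets (-0.015) and NK markers (-0.0083) turned negative. NF-kappaB missed with the values as deposited (-0.12) and both filters (-0.11), and the IL-9 program (0.20) and cytotoxic granules (-0.47) with the filter at the 50th percentile, which left 4 lists under 5 members and without a value and moved the means of type 2 to 1.74, of chemokine receptors to 1.15, of TGF-beta responsive genes to 1.33 and of mast cell markers to -0.0012. Larger means with that filter can follow from its selection, since genes high in Tc9 alone stay and members dim in both groups drop out. Type 1 went to -0.91 with members of a single list. Cholesterol efflux passed as deposited (0.24, also with the block), with median centring (0.23), the filter at the 50th percentile (0.41), a pseudocount of 1 (0.26) and the replicate block (0.23), and the myeloid list as deposited (0.14), with median centring (0.12) and that filter (0.27). The block changed no other list call.

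With an array left out, list means ran from 0.11 to 0.26 for the IL-9 program and -0.15 to -0.067 for NF-kappaB, whose calls were lost in some, and from 0.18 to 0.29 for cholesterol efflux, which passed in 1. Means that changed sign ran from -0.19 to 0.087 for B cell markers, -0.0018 to 0.11 for CD8 identity, -0.058 to 0.080 for NK markers, -0.22 to 0.041 for erythroid markers, -0.11 to 0.061 for immediate early genes and -0.016 to 0.18 for inhibitory receptors. Mast cell markers ran from -0.11 to -0.018. Among 60 named genes the 5 reversals in 1012 values were Cd8a (-0.24 to 0.093), Il10 (-0.35 to 0.22) and Sox13 (-0.43 to 0.053), all with an array left out and none past the threshold; 908 values kept direction and side, 45 lost a call, 26 of them as deposited, and 54 gained 1. Signal over background limits the dim genes, as at most 37.7% of named probe sets lay above the 95th percentile of negative controls.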

Other observations

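The genes in the first 2 paragraphs were chosen after their values were seen, as were both tests of the interferon genes. The tests of Il9 were written down before their results, apart from the comparison of its residual SD and a margin around the threshold.

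H2-DMa, a chain of the chaperone that loads peptides onto class II molecules, rose from 297 ± 43.3 (SD, n = 2) to 1368 ± 111, a log2 change of 2.15 ± 0.17 (limma adjusted p = 0.00399; 2.09 and 2.21 in the pairs numbered 1 and 2). H2-DMb2, a partner chain, rose by 1.98 ± 0.23 (adjusted p = 0.0158), and the near relative H2-DMb1 had 1.13 ± 0.29 (adjusted p = 0.320). The class II genes H2-Aa, H2-Ab1 and H2-Eb1 had log2 changes of 0.35, 0.19 and 0.13, and Ciita, the master regulator of the class II genes, 0.22, none past the threshold; the difference from H2-DMa was not tested, and H2-Ab1, H2-Eb1 and Ciita lay below the 95th percentile of the negative controls on all 4 arrays. H2-Aa, H2-DMb1 and H2-DMb2 lay below it on both Tc1 arrays.

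Ccl17, a ligand of Ccr4, rose by 2.10 on the log2 scale, from 42.6 ± 8.32 to 237 ± 50.3, beside the Ccr8 ligand Ccl1 at 2.09. The growth factor gene Pdgfb rose by 1.74. Ccl17 and Pdgfb lay below the 95th percentile of the negative controls on both Tc1 arrays. The inflammatory chemokines Ccl3 and Ccl4 fell by 0.99 and 1.21, and Ccl3 still measured 4740 ± 829 in Tc9. Dusp4 and Dusp10, phosphatases of MAP kinases, rose by 1.99 and 1.51, while Dusp5 and Dusp6 had 0.0030 and -0.10 and did not pass. Ly6c1 fell by 2.09 beside Ly6c2, and Cd44, the hyaluronan receptor of activated T cells, rose by 1.60. All changes called here lay on the same side in both pairs, which calling genes on these same arrays favours.

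The interferon response list was lower in Tc9 in both pairs. A difference of scale between the arrays is argued against, because the list mean in the values as deposited (-0.64 and -0.72 in the pairs) lay below that of the 200 genes nearest in intensity to each member, by -0.63 and -0.71. An equal fall of interferon-inducible genes of every class stays open, because the genes known mainly from the type I interferon response were too dim. Of 23 measured, 1 (Usp18, -0.58, adjusted p = 0.453) lay above the 95th percentile of the negative controls on all 4 arrays, against 10 of 13 Gbp and Irg GTPases, so the gap of -1.15 between the medians over a mean intensity of 100, in the pair with the smaller gap, decides nothing. Over all members the log2 changes ran from -2.16 to -0.033 for the GTPases and from -1.41 to 0.23 for the type I genes, and these ranges overlap. A biological difference between the cytokine conditions stays open, as untested.

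Il9 was higher on both Tc9 arrays and yet missed the adjusted threshold. As deposited it measured 19.3 and 78.2 in the pair numbered 1 and 30.9 and 102 in the other, below the 95th percentile of the negative controls on all 4 arrays, so that the size of its change could not be measured reliably. It lay at percentiles 61.0 and 59.8 of the negative controls in Tc1 and 91.6 and 89.0 in Tc9. With a pseudocount of 1 the limma adjusted p was 0.0545. By the prediction as written, a value of 0.05 or more goes against compression by the pseudocount. A margin of a factor of 2 around the threshold, not in that prediction, leaves compression undecided. Over all settings the adjusted p ranged from 1.40e-15 to 0.762. Spread between the replicate numbers stays open too: the adjusted p was 5.09e-05 with the replicate block and no intensity trend, but the residual SD of Il9 itself was 0.15 without the block and 0.20 with it, so that p fell through the spread borrowed from other genes.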
